A study of Homo sapiens with 6 samples.

How the data were processed

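The series holds RNA sequencing of the human lung cancer lines A427 and HCC15, each with a control siRNA (Tax), LGR6 siRNA 2 and LGR6 siRNA 4, 1 library per line and siRNA. Cells were collected at 48 h in RPMI with 5% FBS, RNA was purified with a column kit and DNase, and libraries were made with the KAPA mRNA HyperPrep kit, per the labels' protocols. Reads were checked with FastQC 0.11.1, aligned with STAR 2.5.3a and quantified with RSEM 1.3.3 on hg19, per the submitters' processing notes. The annotation used for counting is not given in the sources used here.

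The authors deposited 2 tables of 23686 genes by symbol: expected counts per gene as RSEM estimates them, and TPM. The deposited expected counts are estimates that need not be whole, and 5.75% to 6.29% of values per library were not whole. They were rounded to whole numbers before the tests. The TPM as deposited by the authors served only as an alternative and for the level of LGR6. Gene names were taken from the tables. The counts are on hg19, and the reference annotation used for sequences (GENCODE release 29) is on another build, so no coordinates are given.

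Genes with at least 10 reads in at least 2 of the 6 libraries were tested, which left 14481. Library sizes were scaled by TMM, and edgeR 4.0.16 was fitted with its quasi-likelihood method (glmQLFit without the legacy setting, then glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. CPM are on the TMM scale, except for LGR6 levels with binomial intervals, which use library size alone. LGR6 silencing across both lines used a fit of line plus arm, with 3 residual degrees of freedom, in which the siRNAs count as samples of the silenced group. The responses in A427, in HCC15 and their difference used a fit of line by arm, with 2 residual degrees of freedom. siRNA 4 against siRNA 2, each siRNA against control, and HCC15 against A427 used a fit of line plus siRNA, with 2 residual degrees of freedom. Total counts were 28412000, 25546400 and 26184100 reads in A427 (control, siRNA 2, siRNA 4) and 27589700, 28987900 and 26785100 in HCC15. Intervals for LGR6 are exact binomial (Clopper-Pearson, 95%), and a count of 0 allows 3 counts of the total. No library pair was close enough to be a duplicate, the lowest chi-square per degree of freedom being 59.6. The first principal component held 91.7% of the variance and separated the lines, the second 4.05% and the next 2.39%.

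The siRNA numbers mark the same reagent in both lines, per the labels, and so pair the samples. The difference between siRNA 4 and siRNA 2 correlated between the lines across genes (0.513, and 0.631 over genes with a mean of at least 100 reads). A fit with the siRNA number as a replicate block was therefore set beside the results it changed. Within a line it left fewer than the 2 residual degrees of freedom of the fit of line by arm. For the mean of both siRNAs it was the fit of line plus siRNA. These blocked contrasts were not among those tested on simulated counts.

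Genes were named by a rule written before the data were examined. LGR6 was always named. In each comparison the genes past the threshold with the largest log2 fold change in each direction were named, among those with a mean CPM of at least 1 and a gene symbol, excluding loci without a name and small RNAs: up to 12 per direction across both lines, 6 within a line and 5 elsewhere. For silencing across both lines, or within a line, the change also had to go the same way in every LGR6 siRNA library. Where fewer than 4 genes passed, the 6 with the smallest p were named as not past the test. In each gene list up to 4 members past the threshold, or 2 members not past it, could be named. The genes changed with both siRNAs were named by a rule chosen after the data had been examined: the 10 in each direction whose smaller response was largest. Genes behind counts of 5 or fewer were named after their values were seen. Some members of the gene lists are not reported here.

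The 33 gene lists were written before the data were examined and tested with camera in limma 3.58.1 on the edgeR fit, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists. Members past the threshold were counted over all genes and adjusted over the list alone. The list tests for each siRNA against control and between the lines were added later. Overlap of the siRNA responses was set beside 20 simulated draws without effect. Bootstrap intervals used 1000 draws.

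Each comparison was tested on simulated counts with 200 changed genes, 100 changed 2-fold and 100 changed 4-fold. Across both lines 26% and 96% were recovered, in A427 0% and 56%, in HCC15 0% and 48%, and for the difference between the lines 0% and 0%. For siRNA 4 against siRNA 2 88% and 100% were recovered, for siRNA 2 against control 94% and 100%, for siRNA 4 against control 85% and 100%, and between the lines 97% and 100%. False calls were 4 of 126 calls across both lines, 6 of 62 in A427, 4 of 52 in HCC15 and 0 of 0 for the difference. They were 29 of 217 for siRNA 4 against siRNA 2, 31 of 225 for siRNA 2, 14 of 199 for siRNA 4 and 11 of 208 between the lines, so false calls exceeded the nominal share in most of these tests.

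The siRNA sequences are not given, so 7-mers derived from the responses stand in for guide matches. For genes lower with both siRNAs in HCC15, the expected share with a 7-mer came from genes in the same of 10 bins of UTR length and 5 of GC content. Matches to short sequences were searched in the 3' UTRs of GENCODE release 29 for 10616 genes with a mean of at least 100 reads and a UTR of at least 50 bases. Of the tested genes 87.6% had an annotated 3' UTR. For each of 16382 7-mers present in at least 20 genes, the response of genes with the 7-mer was compared with that of the other genes in each line. In simulated responses 10 of 10 implanted 7-mers (a log2 change of -0.3) ranked first in both lines, and the lowest z over 20 shuffled responses was -4.48.

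Alternatives were DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) for genes with a TPM of at least 1 in 2 libraries, the legacy and robust forms of the edgeR test, median-ratio, upper-quartile and no scaling factors, filters of 1 read in any library or a mean of 100 reads, leaving out each library, fits on the libraries of 1 line, a fit without the line and the fits with the siRNA number as a block. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the UTR search and the plots.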

Results

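RNA sequencing measured gene expression in 6 libraries from 2 human lung cancer cell lines, A427 and HCC15. In each line, 1 library came from cells given a control siRNA (labelled Tax), 1 from cells given LGR6 siRNA 2 and 1 from cells given LGR6 siRNA 4, all at 48 h in medium with 5% FBS. LGR6 is a receptor for R-spondins, secreted proteins that strengthen Wnt signalling. Total counts per library ranged from 25546400 to 28987900 reads, and 14481 of 23686 genes had enough reads to test. The labels do not say whether the libraries came from separate cultures. No 2 libraries shared both line and siRNA, so the p-values do not measure a spread between replicates. In the fit of line plus siRNA, the spread was how far siRNA effects differed between the lines. In the fit of line by arm it was the difference between siRNA 4 and siRNA 2 within each line. The fit of line plus arm added to this the difference between the lines in the response. Each line had 1 control library, whose spread was taken to be like that of the other libraries.

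The target gene was measured first. In HCC15, LGR6 had 257 reads with the control siRNA, 39 with siRNA 2 and 77 with siRNA 4. These were 9.32 CPM of library size (exact 95% binomial interval 8.21 to 10.5), 1.35 (0.957 to 1.84) and 2.87 (2.27 to 3.59). On the normalised scale, siRNA 2 left 14.0% of the control level (9.72% to 19.7%) and siRNA 4 left 30.7% (23.5% to 39.8%). In A427, LGR6 had 5 reads with the control siRNA, or 0.176 CPM of library size (0.0571 to 0.411), and 0 reads with either LGR6 siRNA, which, at 3 reads of the total, allows up to 0.117 CPM of library size with siRNA 2 and 0.115 with siRNA 4. For each siRNA alone the A427 interval reached above the control level (up to 122% with siRNA 2 and 116% with siRNA 4), so neither showed a decrease. A decrease over both LGR6 siRNA libraries of A427 together was not tested. Intervals and limits cover counting error only. Over both lines LGR6 fell by 2.87 on the log2 scale with siRNA 2 (SE 0.36) and by 1.76 with siRNA 4 (SE 0.32), with adjusted p of 0.00379 and 0.00758 by edgeR with Benjamini-Hochberg adjustment. These folds rested on HCC15. When the HCC15 library of the control or of a siRNA was left out, that group's LGR6 level rested on the 5 or 0 reads in A427. DESeq2 put LGR6 at -2.15 with siRNA 4, with an adjusted p of 0.0700 (Benjamini-Hochberg, beside edgeR's value). On log2(TPM + 1) LGR6 stood at -1.01 with siRNA 2 and -0.76 with siRNA 4, and limma gave adjusted p of 0.166 and 0.255, where edgeR had passed both (Benjamini-Hochberg). Without the HCC15 control library LGR6 stood at -5.92 with siRNA 2 and -4.81 with siRNA 4, with adjusted p of 0.308 and 0.332 (edgeR, Benjamini-Hochberg). It was at -4.92 with siRNA 2 without the HCC15 siRNA 2 library (0.374), and with siRNA 4 at -5.12 without the HCC15 siRNA 4 library (0.316) and -1.69 without the A427 control library (0.0822). Among the related receptors, LGR4 had 181 reads in the A427 control library and 2413 in the HCC15 control library, and LGR5 had 1 and 245.

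**Figure D1:**
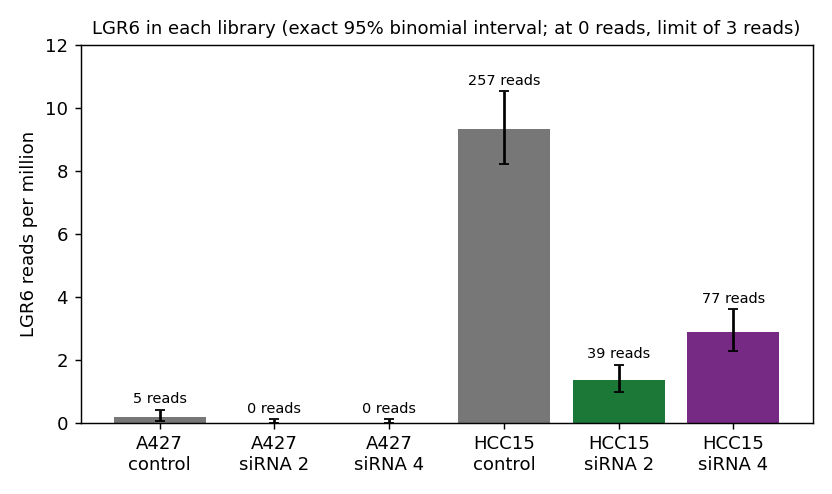
LGR6 CPM of library size in each of the 6 libraries, with the number of reads above each bar and exact 95% binomial intervals as error bars, or at 0 reads the limit of 3 reads. The HCC15 control library stood at 9.32 and the 3 A427 libraries at or below 0.176.

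The main question of the design was which genes respond to silencing of LGR6 in both lines. The genes with the smallest p included CKAP4, which encodes a membrane protein of the endoplasmic reticulum that also acts as a receptor at the cell surface, and RHEB, whose product activates the growth kinase complex mTORC1. Their log2 fold changes were 2.28 (SE 0.21) and 1.60 (SE 0.15), in 4 LGR6 siRNA libraries against 2 control libraries. DDAH1, which degrades natural inhibitors of nitric oxide synthesis, stood at -1.74 (SE 0.15), and the protein kinase gene HIPK3 at -1.49 (SE 0.13). The elongation factor gene ELL2 was at -1.90 (SE 0.20) and FKBP4, an HSP90 co-chaperone gene, at 1.82 (SE 0.20). Each of these 6 genes moved the same way in 4 of 4 LGR6 siRNA libraries against the control of its own line. The naming rule required this, so it adds no evidence. No gene passed the threshold: the adjusted p was 0.0915 for CKAP4, RHEB, DDAH1 and HIPK3 and 0.132 for ELL2 and FKBP4 (edgeR, Benjamini-Hochberg). The edgeR test gave 0 genes at an adjusted p under 0.05, with 1512 genes at an unadjusted p under 0.05 where 724 were expected by chance. Over the same genes limma-voom gave 0 and DESeq2 gave 377 (245 higher and 132 lower), while limma on log2(TPM + 1) gave 1 among genes with a TPM of at least 1 in 2 libraries, the small nucleolar RNA gene SNORD97, which was named after its value was seen. With the siRNA number as a replicate block, the mean of both siRNAs gave 1298 genes, 480 higher and 818 lower, so the count depended on whether differences between the siRNAs were part of the spread. LGR6 stood at -2.29 (SE 0.47) with an adjusted p of 0.170, and at -2.31 with 0.00362 in the blocked fit (edgeR, Benjamini-Hochberg). The blocked adjusted p of CKAP4, DDAH1 and HIPK3 were 0.00167, that of RHEB 0.00202 and those of ELL2 and FKBP4 0.00338 (edgeR, Benjamini-Hochberg).

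Of 33 gene lists fixed before the data were examined, ATF4 and amino acid response genes were lower across both lines, with a median log2 fold change of -0.50 over 24 genes. CHAC1, a glutathione-degrading enzyme gene, was at -1.42 (SE 0.28) and the stress regulator gene NUPR1 at -1.12 (SE 0.25). By camera on the edgeR fit with Benjamini-Hochberg adjustment over the lists, this list had an adjusted p of 2.5e-06, and adjusted p = 0.992 with an estimated correlation. The estimated form rested on few residual degrees of freedom and could hardly pass any list, so its values decide nothing here or below. The list was not among the 5 that passed camera with the preset correlation within A427, while it passed within HCC15. Across both lines 0 of its members passed over all genes, and adjusted over the list alone 1 was higher and 9 were lower. Replication-dependent histones (12 genes, median -0.47), listed as a check on RNA quality and poly(A) selection, and YAP/TAZ targets (23 genes, median -0.27, with AMOTL2 at -0.54 and CTGF at -1.09) were lower, and NRF2 targets (20 genes, median 0.23, with FTL at 0.74 and GCLC at 0.56) were higher. Their camera adjusted p on the edgeR fit (Benjamini-Hochberg) were 0.0087, 0.012 and 0.045, each with an adjusted p = 0.992 with an estimated correlation. In these 3 lists 0 members passed over all genes and 0 adjusted over the list alone. Wnt/beta-catenin targets, the pathway R-spondin receptors act on, had a median of -0.14 over 24 genes and a camera adjusted p of 0.97 on the edgeR fit (Benjamini-Hochberg). That value includes A427, whose control library held 5 LGR6 reads, and RSPO1 to RSPO4 had at most 17 reads in any library. It does not show that loss of LGR6 leaves Wnt targets unchanged. The Wnt feedback genes NKD1 and RNF43 stood at -0.62 (SE 0.19) and 0.47 (SE 0.17), and 0 members passed over all genes or adjusted over the list alone. In the blocked fit of the mean of both siRNAs, NKD1 passed with an adjusted p of 0.0129 (edgeR, Benjamini-Hochberg). So did CHAC1 (0.00872), NUPR1 (0.0155), AMOTL2 (0.0178), CTGF (0.0134), FTL (0.00766) and GCLC (0.0225).

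Within A427 most of the genes that led across both lines led again, with HDAC9 in place of FKBP4 among the 6 with the smallest p. CKAP4 was at 1.98 (SE 0.28), RHEB at 1.44 (SE 0.24), DDAH1 at -1.66 (SE 0.25), HIPK3 at -1.35 (SE 0.21) and ELL2 at -1.59 (SE 0.28), and the histone deacetylase gene HDAC9 at -1.28 (SE 0.22). All 6 had an adjusted p of 1 by edgeR with Benjamini-Hochberg adjustment, over 2 LGR6 siRNA libraries and 1 control library. The edgeR test gave 0 genes, with 389 at an unadjusted p under 0.05, fewer than the 724 expected by chance. limma-voom gave 0, limma on log2(TPM + 1) gave 0, and DESeq2 gave 4, which were CKAP4, DDAH1, FKBP4 and RHEB, named after their values were seen. Fitted with the siRNA number as a replicate block, the count was 0. Histones (12 genes, median -0.64) and mesenchymal genes (16 genes, median -0.35) were lower, as were YAP/TAZ targets (23 genes, median -0.38), among them the receptor kinase gene AXL at -1.19 (SE 0.40). NF-kappaB and inflammatory genes (17 genes, median 0.44) were higher, led by the chemokine gene CXCL1 at 1.61 (SE 0.36), and so were hypoxia and glycolysis genes (21 genes, median 0.09), led by PFKP at 1.12 (SE 0.26). Tested by camera on the edgeR fit with Benjamini-Hochberg adjustment, histones had an adjusted p of 0.0003 and NF-kappaB genes 0.00042, both with an adjusted p = 0.807 with an estimated correlation. The same test gave mesenchymal genes 0.018, YAP/TAZ targets 0.018 and hypoxia genes 0.026 on the edgeR fit (Benjamini-Hochberg), each with an adjusted p = 0.979 with an estimated correlation. In these 5 lists 0 members passed over all genes and 0 adjusted over the list alone. Histones were listed as a check on RNA quality and poly(A) selection, but the cause of their change was not tested. The summed CPM of the 12 genes in A427 was 103 with the control siRNA, 59.9 with siRNA 2 and 93.8 with siRNA 4. In HCC15 it was 191, 198 and 179. Their median log2 ratio to the control library of the line, with 0.1 CPM added to each value, was -0.55 with siRNA 2 and -0.42 with siRNA 4 in A427, and -0.07 and -0.42 in HCC15.

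Within HCC15, which had LGR6 to lose, CKAP4 was at 2.59 (SE 0.29), the zinc finger gene ZNF213 at 2.89 (SE 0.36), ELL2 at -2.19 (SE 0.28), HIPK3 at -1.64 (SE 0.21) and SUZ12, a subunit of the Polycomb repressive complex, at -1.77 (SE 0.23). LGR6 itself stood at -2.17 (SE 0.56), and at -2.27 with an adjusted p of 0.0427 with the siRNA number as a replicate block (edgeR, Benjamini-Hochberg). With that block the adjusted p was 0.0127 for CKAP4, 0.0273 for ZNF213, 0.0263 for ELL2, HIPK3 and SUZ12, 0.0350 for STC2, 0.0340 for ASNS and 0.0426 for CTGF (edgeR, Benjamini-Hochberg). The read-through gene RPL36A-HNRNPH2 shares its reads with its neighbours and is uncertain. Without the block each had an adjusted p of 1 by edgeR with Benjamini-Hochberg adjustment. The edgeR test gave 0 genes, with 535 at an unadjusted p under 0.05, fewer than the 724 expected by chance. limma-voom and limma on log2(TPM + 1) gave 0, and DESeq2 gave 28 (18 higher and 10 lower). With the siRNA number as a replicate block, edgeR gave 114 genes, 27 higher and 87 lower. ATF4 and amino acid response genes were lower (24 genes, median -0.65), led by the hormone gene STC2 at -1.28 (SE 0.23) and asparagine synthetase, ASNS, at -1.46 (SE 0.28). By camera on the edgeR fit with Benjamini-Hochberg adjustment the list had an adjusted p of 3e-11, and adjusted p = 0.971 with an estimated correlation. Over all genes 0 members passed, and adjusted over the list alone 0 were higher and 3 lower. cAMP/CREB targets (13 genes, median -0.51, with CREM at -0.88 and NR4A2 at -1.53) and YAP/TAZ targets (23 genes, median -0.25, with CTGF at -1.50) were lower, and NRF2 targets (20 genes, median 0.33, with OSGIN1 at 1.03) were higher. Their camera adjusted p on the edgeR fit (Benjamini-Hochberg) were 0.018, 0.042 and 0.022, each with an adjusted p = 0.971 with an estimated correlation, and 0 members of these 3 lists passed over all genes or adjusted over the list alone.

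The test of the difference between the lines asked whether HCC15 responded unlike A427. STC2 was at 205 CPM in the HCC15 control library and at 90.0 and 79.3 with the LGR6 siRNAs, beside 14.0, 14.6 and 15.7 CPM in A427, a difference of -1.39 in log2 fold change (SE 0.34). RINL, a Rab activator gene, differed by 2.01 (SE 0.50) and the calcium-binding protein gene TESC by -1.66 (SE 0.43). RPL36A-HNRNPH2, ANKRD20A1 and COMMD3-BMI1 share reads with neighbours or copies and are uncertain. Each had an adjusted p of 1 by edgeR with Benjamini-Hochberg adjustment. The edgeR test gave 0 genes, with 78 at an unadjusted p under 0.05, fewer than the 724 expected by chance. DESeq2, limma-voom and limma on log2(TPM + 1) gave 0. Simulated genes changed 2-fold or 4-fold were not recovered either (0% of 100 each), so differences of that size would have gone uncalled. ATF4 genes (median -0.39, led by STC2 and ASNS) and cAMP/CREB targets (median -0.33, with SIK1 at -1.23) were lower in the HCC15 response, and ER chaperones (median 0.43, with MANF at 0.72) and mesenchymal genes (median 0.31, with MMP14 at 2.13) were higher. By camera on the edgeR fit with Benjamini-Hochberg adjustment the first 3 had adjusted p of 2.2e-05, 0.00017 and 0.00017, each with an adjusted p = 0.668 with an estimated correlation. Mesenchymal genes had 0.00075 by the same edgeR-based test (Benjamini-Hochberg), and adjusted p = 0.689 with an estimated correlation. Of these 4 lists 0 members passed over all genes or adjusted over the list alone.

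The siRNAs are 2 reagents against the same target, whose sequences the labels do not give, and their direct comparison measured what differed between them. In this comparison rose and fell mean higher and lower with siRNA 4 than with siRNA 2, not against the control. FNDC3A, a membrane protein gene, was at 180 CPM with siRNA 2 and 32.1 with siRNA 4 in A427, and at 227 and 19.4 in HCC15, 8.02-fold lower with siRNA 4 (SE 0.23 on the log2 scale). NHLRC3 fell by 2.95 with siRNA 4 (SE 0.20), from 32.2 to 4.89 CPM in A427 and from 28.1 to 3.04 in HCC15. The calcium pump gene ATP2B4 fell by 3.46 (SE 0.33), the metalloproteinase inhibitor gene TIMP3 by 3.78 (SE 0.36) and the myosin kinase gene MYLK3 by 3.33 (SE 0.28). TIMP3 and MYLK3 were at 0.377 CPM or less in A427, so their values came from HCC15. The thrombin receptor gene F2RL2 was higher with siRNA 4 by 5.44 (SE 0.48), and ETNK2, an ethanolamine kinase gene, by 2.86 (SE 0.31). ETNK2 was at 2.86 CPM with siRNA 2 and 13.6 with siRNA 4 in A427, and at 1.02 and 13.5 in HCC15. With the control siRNA it was at 9.86 in A427 and 7.07 in HCC15, so most of this difference was a decrease with siRNA 2. The chloride channel gene BEST3 rose by 3.24 (SE 0.49). It stood at -2.49 without the HCC15 siRNA 4 library, a value that rests on 0 CPM in A427 with either siRNA and gives no direction. SERF1A and TBC1D3 have near-identical copies and are uncertain. The largest adjusted p among these named genes was 0.0038, for BEST3 (edgeR, Benjamini-Hochberg).

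Between siRNA 4 and siRNA 2, 2395 genes passed in edgeR, 1115 higher with siRNA 4 and 1280 lower, with 302 and 482 of them at least 2-fold apart. On log2(TPM + 1) limma gave 687 higher and 1232 lower. The count was 1327 without the A427 control library, 1287 without the HCC15 control library, 713 without the HCC15 siRNA 2 library and 439 without the HCC15 siRNA 4 library. Of 16 LGR receptors and R-spondin partners 0 rose and 2 fell (0 and 4 adjusted over the list alone): LGR4 and LGR5 were lower with siRNA 4, by log2 fold changes of -0.76 (SE 0.14) and -1.02 (SE 0.25), with adjusted p of 0.00979 and 0.0193 (edgeR, Benjamini-Hochberg), and LGR5 was near 0 in A427. LGR6 differed by 1.12 (SE 0.41), with an adjusted p of 0.0906 that did not pass (edgeR, Benjamini-Hochberg). It stood at -2.28 without the HCC15 siRNA 4 library and 3.16 without the HCC15 siRNA 2 library, values that rest on 0 LGR6 reads in A427 and give no direction. Cholesterol synthesis genes were lower with siRNA 4: 0 of 20 rose and 13 fell over all genes, and 17 fell adjusted over the list alone, among them IDI1 at -1.38 and STARD4 at -1.06. Fatty acid synthesis genes followed, with 1 of 12 higher and 6 lower (2 and 8 adjusted over the list alone), among them SCD at -1.77 and FASN at -0.95. Of 40 ribosomal protein genes 16 were higher with siRNA 4 than with siRNA 2 and 0 lower (27 and 0 adjusted over the list alone), with RPL13A at 1.49 and RPS23 at 0.57. Against the control, RPL13A was lower with siRNA 2. Of 18 epithelial genes 0 rose and 5 fell (0 and 9 adjusted over the list alone), with KRT19 at -1.42 and KRT8 at -0.83. Of 23 YAP/TAZ targets 0 rose and 6 fell (1 and 8 adjusted over the list alone), with the growth factor binding protein gene IGFBP3 at -1.88, a value of 0.15 without the HCC15 siRNA 2 library and 0.11 without the HCC15 siRNA 4 library. By camera on the edgeR fit with Benjamini-Hochberg adjustment, cholesterol and ribosomal genes had an adjusted p of 1e-09, fatty acid and epithelial genes 0.0075 and YAP/TAZ targets 0.026, each with an adjusted p = 0.983 with an estimated correlation. Of 24 Wnt/beta-catenin targets 2 rose and 3 fell (6 and 5 adjusted over the list alone), among them WIF1 at 1.87 and CD44 at 0.92, which stood at -0.21 without the HCC15 siRNA 4 library. Of 12 stem cell associated genes 1 rose and 6 fell (1 and 6 adjusted over the list alone), with ITGA6 at -2.04 and LIN28A at -2.51, the latter at 1.67 without the HCC15 siRNA 2 library.

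Each siRNA was then set against the control. CKAP4 rose 5.27-fold with siRNA 2 and 4.42-fold with siRNA 4 (SE 0.17 each on the log2 scale), from 30.6 to 131 and 112 CPM in A427 and from 32.6 to 215 and 177 in HCC15. On the log2 scale RHEB rose by 1.62 and 1.58 (SE 0.14 each), FKBP4 by 1.80 and 1.84 (SE 0.18 each) and ZNF213 by 2.18 and 2.32 (SE 0.31 each). DDAH1 fell by 1.66 and 1.82 (SE 0.14 each), HIPK3 by 1.52 and 1.47 (SE 0.13 each), and CPEB3, a regulator of translation, by 1.96 (SE 0.21) and 2.47 (SE 0.22). ELL2 fell by 1.93 and 1.86 (SE 0.21 each), SUZ12 by 1.36 and 1.52 (SE 0.18 each) and the membrane protein gene SMIM13 by 3.08 (SE 0.29) and 1.43 (SE 0.27). The caveolae gene SDPR fell by 1.85 and 1.73 (SE 0.24 each), a change that HCC15 carried, since SDPR was at 0.137 CPM or less in A427. The other genes named by the rule that rose with both were SNX30, METRNL, TMEFF1, SBK1, LDLRAD3 and FBXW5, and SLC25A30 fell with both. GPR89C has near-identical copies and is uncertain. The largest adjusted p among these genes was 0.0218, for TMEFF1 with siRNA 2 (edgeR, Benjamini-Hochberg).

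With siRNA 2, 1104 genes passed in edgeR (429 higher and 675 lower, against 413 and 393 by limma on log2(TPM + 1)), and with siRNA 4, 1814 (663 higher and 1151 lower). With both, 362 genes passed the same way, 207 higher and 155 lower, 354 of them the same way in 4 of 4 libraries, while 32 passed in opposite ways. More were lower than higher without the A427 siRNA 4 library (168 higher and 182 lower) and without the A427 control library (26 and 28), while limma on log2(TPM + 1) gave 164 higher and 80 lower. Independent lists of these sizes would share 73.3 genes. Because both comparisons used the same control libraries, libraries without any effect were simulated, and they shared a median of 0 and at most 3 genes in 20 draws. The controls could not be split, so part of the excess may come from the shared control libraries. Across genes, the covariance of the siRNA 2 and siRNA 4 responses was 0.0775, against 0.0354 in the simulation, a difference of 0.0421. The Pearson correlation was 0.352, against 0.498 in the simulation, and genes are not independent replicates. The shared count was 1 without the HCC15 control library (CKAP4, named after its value was seen), 54 without the A427 control library, 69 without the HCC15 siRNA 4 library, 108 without the HCC15 siRNA 2 library and 222 without the A427 siRNA 2 library. Without the HCC15 control library siRNA 2 gave 4 genes (CKAP4, SMIM13, TBL1X and LOC100093631, named after their values were seen) and siRNA 4 gave 97. The siRNA 2 count was 127 without the A427 control library, 715 without the A427 siRNA 2 library and 224 without the HCC15 siRNA 2 library, and the siRNA 4 count was 375 without the A427 control library and 244 without the HCC15 siRNA 4 library.

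**Figure D2:**
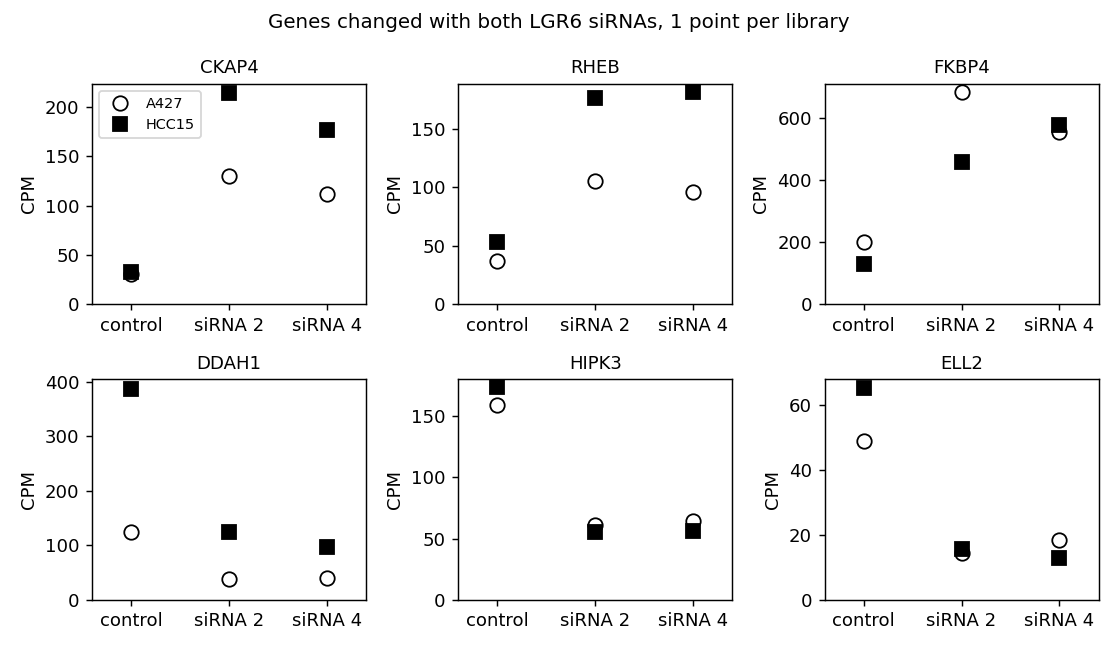
CPM of 6 genes in each library, with open circles for A427 and filled squares for HCC15. CKAP4 went from 30.6 and 32.6 with the control siRNA to between 112 and 215 with the LGR6 siRNAs, and DDAH1 from 124 and 387 to between 38.1 and 125.

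Gene lists were tested for each siRNA after the data had been examined. ATF4 and amino acid response genes were lower with either siRNA. With siRNA 2, 1 of 24 rose and 10 fell (1 and 14 adjusted over the list alone), with CHAC1 at -1.63, the serine synthesis gene PSAT1 at -1.37, NUPR1 at -1.27 and the amino acid transporter gene SLC7A5 at 1.06. With siRNA 4, 1 rose and 7 fell (1 and 10 adjusted over the list alone), with ALDH1L2 at -1.59, CHAC1 at -1.35 and NUPR1 at -0.99. Cholesterol synthesis genes went opposite ways: with siRNA 2, 5 of 20 rose and 0 fell (10 and 0 adjusted over the list alone), with DHCR7 at 0.78 and HMGCS1 at 0.72, and with siRNA 4, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with STARD4 at -1.34. With siRNA 2, ribosomal protein genes (0 of 40 higher and 4 lower, 0 and 11 adjusted over the list alone, with RPL13A at -1.21), apoptosis regulators (0 of 19 higher and 4 lower, 0 and 4 adjusted over the list alone) and histones (0 of 12 higher and 1 lower, 0 and 2 adjusted over the list alone) were lower. With siRNA 4, YAP/TAZ targets (0 of 23 higher and 9 lower, 0 and 10 adjusted over the list alone, with IGFBP3 at -2.08, CTGF at -1.35 and ANKRD1 at -1.28) and epithelial genes (0 of 18 higher and 5 lower, 0 and 7 adjusted over the list alone, with KRT19 at -0.98) were lower. NRF2 targets (4 of 20 higher and 0 lower, 6 and 1 adjusted over the list alone) and NF-kappaB genes (5 of 17 higher and 0 lower, 8 and 0 adjusted over the list alone) were higher. Their leading members changed sign without a single library: AKR1C1, at 1.23, was at -0.36 without the HCC15 control library, and CXCL3, at 1.81, was at -0.36 without the A427 control library, where CXCL1, 2.46-fold higher in the full fit, was at -1.74. By camera on the edgeR fit with Benjamini-Hochberg adjustment the adjusted p with siRNA 2 were 1.3e-05 for ATF4 genes, 2.5e-05 for cholesterol synthesis, 1.1e-06 for ribosomal proteins, 0.012 for apoptosis and 0.042 for histones, each with an adjusted p = 0.998 with an estimated correlation. With siRNA 4 the same edgeR-based test (Benjamini-Hochberg) gave 0.00084 for YAP/TAZ targets, 0.019 for ATF4 genes, 0.031 for cholesterol synthesis, epithelial genes and NRF2 targets, and 0.034 for NF-kappaB genes, each with an adjusted p = 0.976 with an estimated correlation.

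Responses were also compared between the lines without any shared library. Across 14481 genes the A427 and HCC15 responses to the same siRNA had a Pearson correlation of 0.430 for siRNA 2 and 0.532 for siRNA 4 (Spearman 0.459 and 0.564). Responses to different siRNAs, which share the target and the control siRNA, had 0.170 and 0.154 (Spearman 0.211 and 0.166). No p-value was computed, since genes are not independent replicates.

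**Figure D3:**
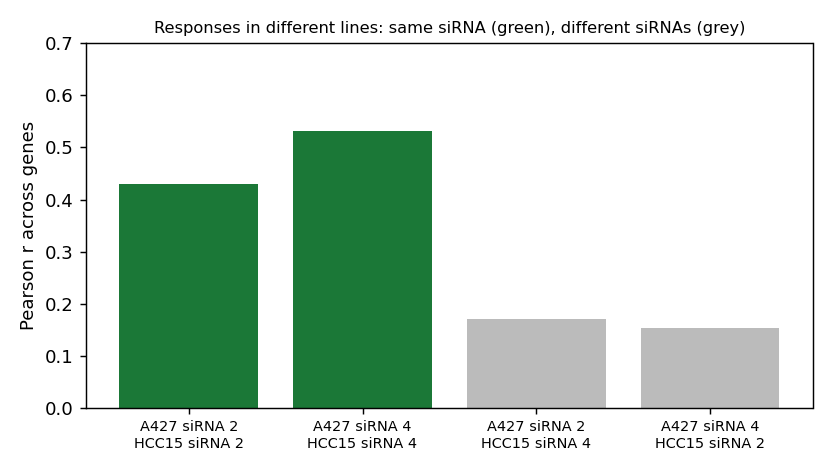
Pearson correlation across 14481 genes between a response in A427 and a response in HCC15, each an LGR6 siRNA library against the control of its own line. Bars for the same siRNA stood at 0.430 and 0.532, and bars for different siRNAs at 0.170 and 0.154.

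The lines themselves differed far more than the siRNAs. In the means that follow, the n = 3 were the libraries of a line with the control siRNA and with each LGR6 siRNA. Their SD therefore includes siRNA effects and does not measure a spread between replicates. HCC15 expressed the aldehyde dehydrogenase gene ALDH3A1 at 62.2 ± 9.60 CPM (SD, n = 3), the metallothionein gene MT1E at 103 ± 14.2, BHMT2 at 167 ± 45.1, MALL at 252 ± 55.0 and GRAMD1B at 480 ± 179, each at 0.1 CPM or less in every A427 library. A427 expressed the protease inhibitor gene SERPINB2 at 1813 ± 231 CPM, the membrane peptidase gene MME at 2324 ± 376, the glucagon gene GCG at 443 ± 64.8, the cancer-testis gene MAGEA4 at 383 ± 8.97 and MMRN1 at 147 ± 33.4, each at 0.14 CPM or less in every HCC15 library. LGR6, LGR4 and LGR5 were higher in HCC15, with log2 fold changes of 6.25 (SE 0.43), 4.01 (SE 0.12) and 8.19 (SE 0.36). Of 14481 genes 11073 passed in edgeR, 5386 higher and 5687 lower in HCC15, and the largest adjusted p among the genes named in this paragraph was 4.5e-07, for LGR6 (edgeR, Benjamini-Hochberg).

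The lists were also tested between the lines after the data had been examined. NRF2 targets were higher in HCC15, with 19 of 20 higher and 1 lower, among them AKR1C1 at 7.88 and ABCC2 at 10.01. ATF4 genes (19 of 24 higher, 3 lower, with PHGDH at 4.04 and NUPR1 at 5.94), extracellular matrix and invasion genes (10 of 15 and 4, with PLAU at 10.62 and TIMP1 at 8.99), YAP/TAZ targets (16 of 23 and 4, with TGFB2 at 5.45), G2/M genes (22 of 30 and 3) and mesenchymal genes (11 of 16 and 4) were also higher. Lower were p53 targets (2 of 25 higher and 17 lower, with EDA2R at -3.89), NF-kappaB genes (2 of 17 and 12, with CXCL1 at -6.90), cholesterol synthesis (1 of 20 and 17, with DHCR7 at -3.28), fibroblast markers (0 of 6 and 5, with COL3A1 at -7.58) and ER chaperones (3 of 18 and 11). Adjusted over the list alone, the lower counts were 4 for ATF4 and G2/M genes and 13 for NF-kappaB genes, and every other count in these 11 lists was as given. With camera on the edgeR fit and Benjamini-Hochberg adjustment, NRF2 targets had an adjusted p of 2.2e-10, and the other lists lay between 0.00032 (p53 targets, ATF4 genes, YAP/TAZ targets and extracellular matrix genes) and 0.031 (mesenchymal genes). In between, the edgeR-based test (Benjamini-Hochberg) gave an adjusted p of 0.00036 for G2/M genes, 0.0014 for NF-kappaB genes, 0.002 for cholesterol synthesis, 0.007 for fibroblast markers and 0.0095 for ER chaperones, and each of the 11 lists had an adjusted p = 0.876 with an estimated correlation. In the 8 contrasts, 0 calls by camera on the edgeR fit fell on the lists of LGR receptors and R-spondin partners, Wnt/beta-catenin targets, G1/S and DNA replication, interferon-stimulated genes, ERK output, TGF-beta and BMP targets, Notch targets, lung lineage, neuroendocrine and stem cell associated genes, small RNA pathway components, oxidative phosphorylation, heat shock, endothelial markers and immune cell markers. The lowest adjusted p among them was 0.070, for heat shock genes across both lines (edgeR fit, Benjamini-Hochberg), and all 33 lists had enough tested genes to be used.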

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

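Chosen after the results were seen were the tests of silencing depth by slope, over the called genes and over the genes at least 2-fold apart in HCC15 or in A427 (for A427 the bounds of 0.25 and 0.5 were set with the slope already known), and the test of the other strand of siRNA 2. The response to LGR6 siRNA 4 differed from the response to LGR6 siRNA 2 for 2395 genes, a difference between groups that edgeR tested directly (Benjamini-Hochberg adjustment), although both siRNAs lower the same target.

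Different scaling does not account for the 2395 genes, since the lowest count under 3 other scalings was 2249. Different depth of LGR6 silencing predicts a small difference in A427, where LGR6 was nearly absent. Over the called genes the slope of the A427 on the HCC15 difference was 0.631 (0.608 to 0.655). This decides nothing, because calling them needs the lines to move alike. Over 1223 genes at least 2-fold apart in HCC15 the slope was 0.459 (0.427 to 0.491), between the bounds of 0.25 and 0.5 set for it. So for both sets of genes a part played by silencing depth cannot be told apart from other differences. Depth alone would move a gene the same way with both siRNAs against the control. While 362 genes passed the same way, 32 passed in opposite ways, which argues against depth as the whole cause for these 32. In HCC15 siRNA 2 left 14.0% of the control LGR6 level and siRNA 4 left 30.7%. More genes passed with siRNA 4 (1814) than with siRNA 2 (1104), but with 1 HCC15 library per siRNA this order decides nothing. Over 499 genes at least 2-fold apart in A427, chosen without HCC15, the slope of the HCC15 on the A427 difference was 0.868 (0.733 to 0.977). Of these genes, 90.6% had the same sign in both lines. The bounds were set with this slope known, so passing them decides nothing. Read without bounds, differences found where the control library held 5 LGR6 reads recurred in HCC15. That recurrence argues against silencing depth as the whole cause for these 499 genes. A candidate explanation is silencing of other transcripts through guide matches in their 3' UTRs: the 7-mer most tied to lower expression in A427 ranked 1 of 16382 in HCC15 for siRNA 4 (ATGGATA, in 1179 genes) and 1 for siRNA 2 (GTGATTC, in 1457 genes), and 2 of these 2 leading 7-mers occur in an annotated LGR6 transcript, as 21.2% of all 7-mers do. Against control in HCC15, genes with ATGGATA stood at a mean of -0.447 with siRNA 4 (SE 0.021), against -0.0113 without it. With siRNA 2 they stood at -0.0261. Genes with GTGATTC stood at -0.215 with siRNA 2 (SE 0.0157), against 0.0197 without it, and at -0.0937 with siRNA 4. The siRNA sequences are not known, so that these 7-mers are guide matches was not shown. Another 7-mer family of siRNA 2 (AGCTCTT) may mark its other strand, whose match and the leading one spanned 17 bases in LGR6 transcripts, outside the 19 to 23 bases set for it, a range that did not allow for matches that start at the second base of each strand.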

How the results depend on the processing

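Chosen after the data had been examined were the fit of the mean of both siRNAs with the siRNA number as a block, and the gene list tests for each siRNA and between the lines. Across both lines, within each line and for the difference between the lines, edgeR counts were 0 in the main test. DESeq2 gave 377 across both lines (245 higher, 132 lower), 4 in A427 (3 higher, 1 lower) and 28 in HCC15 (18 higher, 10 lower), and limma on log2(TPM + 1) gave 1 across both lines. The siRNA number as a replicate block gave 114 in HCC15 (27 higher, 87 lower) and, for the mean of both siRNAs, 1298 (480 higher, 818 lower), by construction because differences between the siRNAs then leave the spread. With the block edgeR gave 0 in A427 (1598 at an unadjusted p under 0.05) and 0 for the difference (243), and the other comparisons already held the siRNA in the fit. The other tools, filters and scalings kept these counts at 0 and every other count of genes within 1.5 times. The cause of the DESeq2 and limma differences was not tested.

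On log2(TPM + 1) the split of calls moved by over 10 points: 687 higher and 1232 lower against 1115 and 1280 for siRNA 4 against siRNA 2, 413 and 393 against 429 and 675 for siRNA 2, and 164 and 80 against 207 and 155 for both siRNAs. Without scaling factors the median of all genes between the lines moved by -0.10. With an estimated correlation 0 lists passed in each of the 8 contrasts, against 4 across both lines, 5 in A427, 4 in HCC15, 4 for the difference, 5 for siRNA 4 against siRNA 2, 5 for siRNA 2, 6 for siRNA 4 and 11 between the lines. The mean correlation between the lines for the same siRNA was 0.481, and 0.563 with a prior count of 10, 0.624 over genes with a mean of at least 100 reads and 0.616 on log2(TPM + 1). For different siRNAs it was 0.162, and 0.194, 0.208 and 0.211. The cause was not tested. LGR6 in HCC15 kept 14.4% and 30.9% of control by library size and 15.3% and 28.6% by TPM.

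Leaving out each library gave 0 to 0 genes across both lines, in A427, in HCC15 and for the difference. Counts ranged from 1 to 350 for both siRNAs, 4 to 1438 for siRNA 2, 97 to 2098 for siRNA 4, 439 to 2220 for siRNA 4 against siRNA 2 and 9461 to 10588 between the lines. The lowest for both siRNAs and for each siRNA came without the HCC15 control library, and the lowest for siRNA 4 against siRNA 2 without the HCC15 siRNA 4 library. Fewer samples then carry each contrast. No value was possible for A427 or the difference without the A427 control library, or for HCC15 or the difference without the HCC15 control library. Gene values changed sign as follows, with the range over left-out libraries in brackets. Between siRNA 4 and siRNA 2, LGR6 was at -2.28 (-2.28 to 3.16), BEST3 at -2.49 (-2.49 to 4.43), CD44 at -0.21 (-0.21 to 0.98) and IGFBP3 at 0.11 without the HCC15 siRNA 4 library, and IGFBP3 at 0.15 (-2.003 to 0.15) and LIN28A at 1.67 (-3.36 to 1.67) without the HCC15 siRNA 2 library. Without the HCC15 siRNA 4 library, siRNA 4 was left with A427, where LGR6 had 0 reads and BEST3 0 CPM with either LGR6 siRNA. The values of LGR6 and BEST3 there rest on these zeros and give no direction. With siRNA 2, CXCL1 was at -1.296 without the A427 control library (-1.296 to 1.83) and -0.28 without the A427 siRNA 2 library, where CXCL3 was at -2.63 (-2.63 to 2.49). With siRNA 4, CXCL1 was at -1.74 (-1.74 to 1.38) and CXCL3 at -0.36 (-0.36 to 3.55) without the A427 control library, and AKR1C1 at -0.36 (-0.36 to 1.27) without the HCC15 control library. The cause of the sign changes other than those of LGR6 and BEST3 was not tested. LGR6 lost its call for siRNA 4 under DESeq2 (log2 fold change -2.15, adjusted p 0.0700). It also lost both calls on log2(TPM + 1), where limma gave adjusted p of 0.166 and 0.255 (Benjamini-Hochberg). It lost both calls without the HCC15 control library (0.308 and 0.332), that for siRNA 2 without the HCC15 siRNA 2 library (0.374), and that for siRNA 4 without the HCC15 siRNA 4 library (0.316) or the A427 control library (0.0822). With the siRNA number as a block it passed in HCC15 (0.0427) and for the mean of both siRNAs (0.00362), as NKD1, CHAC1, NUPR1, AMOTL2, CTGF, FTL and GCLC did for that mean, and it passed across both lines with DESeq2 (0.0210).

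Of the named genes under all alternatives, 83 of 573 values for siRNA 2, 95 of 604 for siRNA 4 and 45 of 414 for siRNA 4 against siRNA 2 kept their direction and no longer passed. Across both lines 26 of 269, in A427 3 of 184 and in HCC15 14 of 203 now passed, and 382 of 382 between the lines stayed as they were. Depth limits LGR6 in A427, at 5 reads with the control siRNA and 0 with either LGR6 siRNA. When the HCC15 library of the control or of a siRNA was left out, that group's LGR6 level rested on these counts.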

Other observations

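Chosen after the results were seen were the test of the 144 genes changed 2-fold in HCC15, the test of 7-mer matches in genes lower with both siRNAs in HCC15, and the choice of the genes named in this part. With siRNA 2 the mitotic regulator genes FOXM1, AURKA and TOP2A fell by 1.27 (SE 0.17), 1.04 (SE 0.14) and 0.78 (SE 0.15), and with siRNA 4 the cyclin genes CCNE2 and CCNA2 fell by 1.45 (SE 0.17) and 0.65 (SE 0.11). NUSAP1, a spindle gene, rose by 1.09 and 0.93 (SE 0.18 each) and the DNA methylation cofactor gene UHRF1 by 0.61 and 1.13 (SE 0.15 each). Each of these genes passed in edgeR with its siRNA. The G2/M list as a whole had camera adjusted p of 0.35 and 0.73 on the edgeR fit (Benjamini-Hochberg).

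The apoptosome gene APAF1 fell with both siRNAs, by 0.81 and 1.53 (SE 0.14 each). In the small RNA pathway AGO1 rose by 0.64 with siRNA 2 (SE 0.11), and with siRNA 4 TNRC6A rose by 0.87 (SE 0.11) and DICER1 fell by 0.86 (SE 0.18).

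The 362 genes changed the same way with both LGR6 siRNAs could reflect loss of LGR6. Over these genes the median ratio of the A427 to the HCC15 response was 0.845 (0.815 to 0.895), which decides nothing, because calling them needs the lines to move alike. Over 144 genes changed at least 2-fold the same way with both siRNAs in HCC15, chosen without A427, the median share seen in A427 was 0.573 (0.522 to 0.632), with 88.2% of the same sign. With 5 LGR6 reads in the A427 control library, this share argues against loss of LGR6 as the whole cause for these 144 genes. Of 76 genes chosen in A427 in the same way, the share seen in HCC15 was 0.707 (0.489 to 0.885), so choosing genes in 1 line can shrink the share in the other, and 0.573 does not measure a part due to LGR6 in HCC15. A response to the few LGR6 transcripts in A427 was not tested.

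The shared control libraries alone gave at most 3 shared genes in 20 simulated draws, but with 1 control library per line the spread between real control libraries was not measured, and simulated libraries need not vary like real ones, so their part stays open. Of 129 genes lower with both siRNAs, 31.0% held leading 7-mers of both LGR6 siRNAs in their 3' UTR, 4.11 times the share among 10616 genes (7.55%), a value that decides nothing, because the 7-mers came partly from the same libraries and UTR length was not matched. Of 68 genes at least 2-fold lower with both siRNAs in HCC15, 30.9% held the 7-mers that lead in A427 for both, 2.36 times (1.64 to 3.21) the 13.1% expected from their UTR length and GC content. For single siRNAs the same ratio was 1.75 (1.46 to 2.05) for the siRNA 2 7-mers and 1.39 (0.991 to 1.75) for those of siRNA 4, an interval that includes 1. Silencing of the same transcripts by both siRNAs is a candidate explanation for part of these genes, although the siRNA sequences are not known. The 7-mer most tied to higher expression with both LGR6 siRNAs than with the control in A427 (TGTCCAT, in 1447 genes) ranked 1 in HCC15, so an effect of the control siRNA through guide matches may add to the genes changed the same way with both LGR6 siRNAs. The shift was small, and in HCC15 uneven. Against control, genes with TGTCCAT stood in HCC15 at a mean of 0.076 with siRNA 2 (SE 0.014) against -0.0265 without the 7-mer. With siRNA 4 in HCC15 they stood at -0.0415 (SE 0.0164) against -0.0625. In A427 they stood at 0.0231 with siRNA 2 (SE 0.0118) against -0.0325, and at 0.00387 with siRNA 4 (SE 0.0129) against -0.0302. Of 193 genes higher with both, 40.9% held a control 7-mer, 1.98 times the share among all genes (20.7%), but the 7-mers were chosen from the same libraries, and for these genes that effect cannot be told apart from others.

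Between HCC15 and A427 11073 genes passed, and the highest count in the other splits of the 6 libraries into 3 and 3 was 0. The real split was 1 of 10, too few for a share under 0.05.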
